A study of Homo sapiens with 6 samples.

How the data were processed

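The arrays profiled total RNA of 6 samples of CA2-derived airway epithelium, 2 for each of control, TNF-alpha and LPS. The authors deposited 1 table of log2 values with 33297 rows and 6 columns, each column naming 1 array. RMA and Partek 6.6 are named per the submitters' processing notes. Further settings are not given in the sources used here. Array medians lay between 6.95 and 7.05 and values between 2.57 and 13.8, so no transformation was applied. Groups and replicate numbers were taken from the sample titles.

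Rows were named through the platform annotation supplied with the table. Of the rows 19460 named 1 gene, 1754 named several and 12083 were not listed, and rows of the last 2 kinds were left out of the gene tests. Entrez identifiers of 19429 rows were found in the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. The array's genome build is not given in the sources used here, so no coordinates are printed. For the 769 genes with several rows, the row with the highest mean over the 6 arrays stood for the gene, which left 18417 genes.

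Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 6 arrays and empirical Bayes moderation (3 residual and 2.45 prior degrees of freedom). The 3 differences (TNF-alpha minus control, LPS minus control, TNF-alpha minus LPS) were tested two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. An exact permutation test of 2 against 2 arrays cannot give a p under 0.333. Folds are 2 to the power of a difference of mean log2 values.

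Before the data were examined, 28 gene lists with 615 entries were fixed, of which 557 were measured by a row naming 1 gene. They covered NF-kB targets, cytokines, interferon-stimulated genes, MHC class I, LPS sensing, TNF receptor signalling, adhesion and proteases, antimicrobial defence, immediate-early genes, and stress and metabolism (endoplasmic reticulum, oxidative, hypoxia, cholesterol synthesis, housekeeping). Others held markers of airway (secretory, ciliated, basal, ion transport, junctions, lung endoderm) and of other cells (pluripotent, proliferating, mesenchymal, neural, liver and gut, leukocyte, endothelial, squamous). Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists in each comparison. Camera with an estimated correlation and fry were alternatives, and none of the calls held with an estimated correlation. Median, mean and test of a list differed in sign for 2, 2 and 6 lists in the 3 comparisons, of which 0 had passed. They were the ciliated and housekeeping lists after TNF-alpha, the junction and endothelial lists after LPS, and the basal, ion transport, liver and gut, endoplasmic reticulum, oxidative stress and cholesterol lists between the stimuli.

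Named genes followed a rule fixed before the data were examined. It took up to 12 rises and 8 falls among genes past the threshold with separated arrays. Where fewer than 5 passed, it took the 10 smallest unadjusted p with separated arrays, and from each described list up to 4 members with the smallest p. It also took 15 genes of the NF-kB response, LPS and TNF sensing and airway identity, of which MUC5AC was not analysed here. AFP, COL3A1 and DPPA4, and the levels of marker genes on single arrays, were chosen after their values were seen.

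The tests were run first on simulated data with the real means and residual spreads. Of 50 genes changed 4-fold in TNF-alpha against control among 18417, 32 were recovered, and 40 of 50 changed 8-fold. The numbers were 25 and 35 for LPS against control and 28 and 41 for TNF-alpha against LPS. A list shifted by 1 log2 unit was called in each comparison, and 0 of 27 unchanged lists were. Genes varied independently in the simulations, and each had 1 spread for all groups. The array pairs contradict a like spread, with SDs of differences of 0.78 for control, 0.14 for TNF-alpha and 0.50 for LPS. The numbers recovered, and the absence of calls among unchanged lists, may therefore not hold for these arrays.

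Alternatives covered the replicate block, the arrays in the fit, the prior variance, moderation, filters on dim genes, rows per gene, normalization, the threshold and leaving out each array. After the data were seen, array weights, a fit of replicate 1 of control and LPS with both TNF-alpha arrays (the second replicates of control and LPS left out together) and simulations of unchanged groups with each group's own spread were added. In that fit the spread comes from the TNF-alpha pair alone, which may hold technical spread only. With an estimated correlation 0 lists passed in every fit with arrays left out. Leaving out an array leaves a group with 1 array, which is assumed to vary like the others.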

Results

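Gene expression was measured on 6 whole-transcript arrays of airway epithelial cultures that had been differentiated from CA2, a human embryonic stem cell line, by withdrawal of basic FGF and culture at an air-liquid interface. The arrays formed 3 groups of 2: unstimulated control cultures, cultures given 10 ng/ml of the inflammatory cytokine TNF-alpha, and cultures given 5 µg/ml of LPS, the bacterial outer-membrane ligand of TLR4. Both challenges lasted 5 hours. The design asks how stem cell-derived airway cells answer an innate immune challenge, and whether both stimuli give a like answer. Values are log2 expression, and 18417 genes were tested. The number of arrays limits the precision of every value, and p-values measure only the spread between these arrays, which may be technical.

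Markers of several lineages were measured. On the array labelled control replicate 1, AFP, the fetal serum protein alpha-fetoprotein, had a log2 value of 11.84 and SERPINA1, another liver gene, one of 8.84. The collagen gene COL3A1 stood at 12.16 and the fibronectin gene FN1 at 13.05. Among airway markers, the ciliated cell regulator FOXJ1 stood at 7.02, the club cell secretoglobin SCGB1A1 at 6.72, the chloride channel gene CFTR at 5.63 and the basal keratin gene KRT5 at 7.50. Levels of different genes come from different probes, so these values put the lineages in no order. Over the 6 arrays the list of ciliated cell markers averaged between 6.43 and 6.57, and that of epithelial junctions and keratins between 10.21 and 10.59.

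The array labelled control replicate 2 stood apart from the other 5. Its correlation with them over all genes was between 0.862 and 0.906, while control replicate 1 and the TNF-alpha arrays correlated at 0.985 to 0.986. The mean of 18 pluripotency markers was 9.71 on it and 7.04 on control replicate 1. LIN28A, an RNA-binding protein of stem cells, stood at 12.35 against 8.19, and DPPA4 at 11.67 against 7.33. Conversely, AFP stood at 6.47 against 11.84, and the liver and gut list averaged 6.25 against 9.41. The array labelled LPS replicate 2 stood apart to a smaller degree, with KRT5 at 11.75 against 7.61 on LPS replicate 1. The TNF-alpha arrays were the closest pair, with r = 0.997 and an SD of their differences of 0.136 log2 units, against 0.781 for the control pair and 0.502 for the LPS pair. They held identical values at 18 of 33297 probe sets, where other pairs of arrays held 5 to 24, and were counted as 2 arrays. Whether they come from separate cultures is not given in the sources used here, so the SDs after TNF-alpha may hold technical spread alone.

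**Figure D1:**
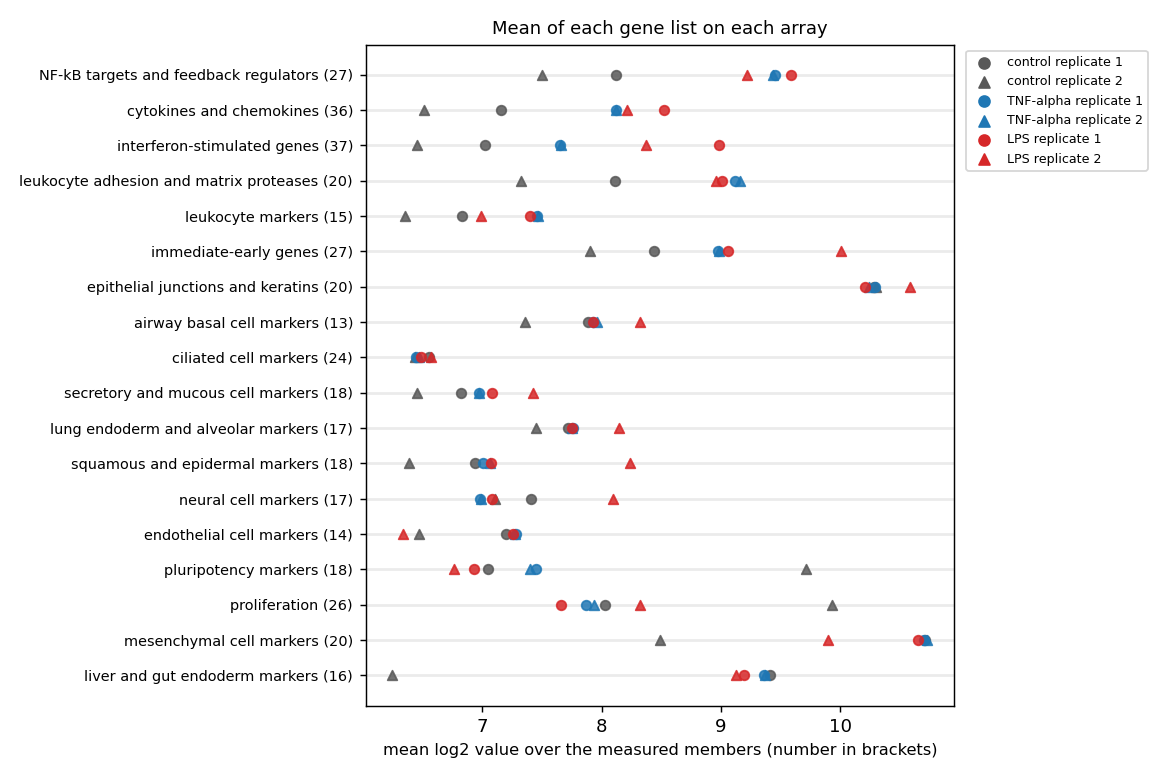
Mean log2 value (horizontal axis) over the measured members of 18 gene lists on each of the 6 arrays; gray, blue and red mark control, TNF-alpha and LPS, and circles and triangles mark replicates 1 and 2. The pluripotency mean of control replicate 2 lies at 9.71, while the other 5 arrays lie between 6.76 and 7.45.

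TNF-alpha against control asked which genes the cytokine moved. The NF-kB targets and feedback regulators were higher after TNF-alpha: all 27 measured members lay above control in mean. On all 27 both TNF-alpha arrays exceeded both control arrays, against 22.7% of all genes tested. NFKBIA, the inhibitor that NF-kB itself induces, was at 10.40 ± 0.45 in control and 12.46 ± 0.02 after TNF-alpha (SD, n = 2), a 4.16-fold difference. PTGS2, the inducible cyclooxygenase, was 7.97-fold higher, the feedback regulator TNIP1 2.70-fold and the NF-kB subunit gene REL 2.64-fold. TNFAIP3, which encodes the A20 feedback inhibitor, was at 8.46 ± 1.30 in control and 11.77 ± 0.00 after TNF-alpha. The median difference of the list was 1.40 log2 units, and 1.29 against control replicate 1 alone. Of its members 23 passed when adjusted over the list alone and 0 over all genes tested. The list passed as a set by limma's camera (adjusted p = 1.65e-27), and did not with an estimated correlation (adjusted p = 0.324).

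Of 36 measured cytokines and chemokines, 32 lay above control in mean. Of the 36, 16 passed as higher when adjusted over the list alone, 0 over all genes, and 20 passed neither. CXCL8, the neutrophil attractant interleukin 8, was at 7.34 ± 0.40 in control and 10.23 ± 0.05 after TNF-alpha. IL1A was 13.0-fold higher, CCL20 7.30-fold and IL32 2.86-fold, and IL6 was 4.11-fold higher. The list gave a camera adjusted p of 4.61e-16 (adjusted p = 0.324 with an estimated correlation). Among 20 genes of leukocyte adhesion and matrix proteases, 11 passed when adjusted over the list alone. The adhesion receptors VCAM1 and ICAM1 were 15.8-fold and 11.4-fold higher, the urokinase gene PLAU 5.03-fold and the collagenase gene MMP1 5.52-fold. That list gave an adjusted p of 1.73e-14, and an adjusted p of 0.324 with an estimated correlation.

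In each of 4 lists of defence and sensing genes, few members passed over the list. Of 27 antimicrobial and mucosal defence genes, 3 passed when adjusted over the list alone: the complement genes C3 and CFB, at 4.36-fold and 8.80-fold, and the calprotectin subunit gene S100A9, at 2.78-fold (camera adjusted p = 6.76e-10; adjusted p = 0.324 with an estimated correlation), and 1 lay below control in mean. Of 37 interferon-stimulated genes, 3 passed when adjusted over the list alone, namely IRF1 at 3.01-fold, IFI44 at 1.87-fold and GBP2, at 6.44 ± 1.17 in control and 9.44 ± 0.06 after TNF-alpha (camera adjusted p = 6.34e-15; adjusted p = 0.324 with an estimated correlation), and 4 members lay below control in mean. The peptide transporter gene TAP1, 3.09-fold higher, was the single member of 12 measured MHC class I genes to pass over its list (camera adjusted p = 3.8e-05; adjusted p = 0.324 with an estimated correlation). Among 17 genes of LPS sensing, the co-receptor gene CD14 passed over the list, at 6.68 ± 0.60 in control and 8.64 ± 0.19 after TNF-alpha. TLR4 stood at 5.66 ± 0.27 and 5.87 ± 0.10, and LY96, its partner, at 4.33 ± 0.09 and 4.60 ± 0.01. That list, of which 3 members lay below control in mean, gave a camera adjusted p of 8.43e-05, and an adjusted p of 0.324 with an estimated correlation. The TNF receptor signalling list did not pass (adjusted p = 0.0686), with TNFRSF1A at 9.84 ± 0.77 in control and 10.63 ± 0.04 after TNF-alpha. It passed without TNF-alpha replicate 2 (adjusted p = 0.0342), and without the second replicates of both control and LPS (adjusted p = 0.0333), where its median went from 0.26 to 0.08.

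All 15 measured leukocyte markers lay above control in mean after TNF-alpha, and 6 passed when adjusted over the list alone, among them the Fc receptor chain gene FCER1G at 3.87-fold, CD53 at 3.30-fold, LAPTM5 at 4.20-fold and PTPRC, which encodes CD45, at 1.71-fold. The list's camera adjusted p was 5.14e-11 (adjusted p = 0.324 with an estimated correlation). Against control replicate 1 alone the median of the list was 0.53 log2 units. Of 27 immediate-early genes, 0 passed over the list, with DUSP6 2.41-fold higher and ZFP36, which destabilizes cytokine mRNA, 5.24-fold higher (camera adjusted p = 6.71e-09; adjusted p = 0.344 with an estimated correlation). On each of the 9 lists named so far that passed, control replicate 2 differed from control replicate 1 in mean by -0.41 log2 units (MHC class I) to -0.79 (adhesion and proteases). Against control replicate 1 alone the medians were smaller, at 0.51 for interferon-stimulated genes (0.91 against both), 0.81 for adhesion and proteases (1.21), 0.26 for antimicrobial genes (0.46), 0.19 for MHC class I genes (0.33), 0.13 for LPS sensing (0.27) and 0.43 for immediate-early genes (0.74). Folds of single genes after either stimulus use the mean of both control arrays too. Where control replicate 2 was the lower, they exceed those against control replicate 1 alone. The antimicrobial median was 0.72 without control replicate 1. The numbers passing over the list alone also moved. Without either TNF-alpha array they fell to 14 NF-kB genes, 5 cytokines, 1 antimicrobial gene, 1 leukocyte marker and 0 interferon-stimulated, MHC class I, LPS-sensing and adhesion genes. Without control replicate 1 they were 27 cytokines, 9 antimicrobial, 21 interferon-stimulated, 5 MHC class I, 3 LPS-sensing and 9 immediate-early genes, and without control replicate 2 they were 10 cytokines, 2 antimicrobial genes, 2 leukocyte markers, 1 immediate-early gene and 0 MHC class I genes. Without either LPS array they were 9 interferon-stimulated genes, 3 leukocyte markers and 2 LPS-sensing genes.

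Outside the inflammatory lists, single epithelial genes stood out. CLDN1, a tight junction claudin, was at 8.29 ± 0.15 in control and 10.65 ± 0.07 after TNF-alpha, and was the single member of 20 epithelial junction and keratin genes to pass over its list, which did not pass as a set (adjusted p = 0.388). MUC1, a membrane mucin, was 1.92-fold higher and the single one of 18 secretory and mucous genes to pass over its list (camera adjusted p = 0.0036; adjusted p = 0.395 with an estimated correlation), whose median was 0.29, and 0.08 against control replicate 1 alone. No member passed in the ciliated list of 24 (adjusted p = 0.83), the basal list of 13 (adjusted p = 0.075), the ion and water transport list of 20 (adjusted p = 0.0515) or the lung endoderm and alveolar list of 17 (adjusted p = 0.0694). FOXJ1 stood at 6.76 ± 0.38 in control and 6.96 ± 0.13 after TNF-alpha, SCGB1A1 at 6.50 ± 0.31 and 6.80 ± 0.03, CFTR at 5.25 ± 0.54 and 5.81 ± 0.02, and KRT5 at 7.01 ± 0.70 and 7.30 ± 0.03. Of these, the transport list passed without either TNF-alpha or either LPS array (adjusted p = 0.0362 to 0.0486), the basal list without TNF-alpha replicate 1 (0.0486), and the lung list without control replicate 1 (0.0319) or TNF-alpha replicate 2 (0.0422). The neural list did not pass (adjusted p = 0.202), and did as lower without control replicate 2, with a median of -0.35 (adjusted p = 0.00269), also where LPS replicate 2 was left out as well (adjusted p = 3.34e-06). Without control replicate 1, 4 secretory, 3 basal, 6 transport and 2 lung genes passed over their lists, 1 transport and 1 lung gene did without control replicate 2, and without any single TNF-alpha or LPS array 0 secretory genes did. Also not past the threshold were the endoplasmic reticulum stress (adjusted p = 0.286), oxidative stress and metallothionein (0.122) and housekeeping (0.6) lists.

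A further group of lists moved with the array labelled control replicate 2. Pluripotency markers had a median difference of -1.25 log2 units (camera adjusted p = 0.00911; adjusted p = 0.578 with an estimated correlation), and against control replicate 1 alone it was 0.18, in the opposite direction (camera adjusted p = 4.76e-06). Proliferation genes had a median of -1.10 (adjusted p = 8.7e-08; 0.439 with an estimated correlation). Against control replicate 1 alone it was -0.11, and the list did not pass without control replicate 2 (adjusted p = 0.316) but did when LPS replicate 2 was left out too (adjusted p = 0.0351). The liver and gut list had a median of 1.76 (adjusted p = 5.59e-05) and the mesenchymal list one of 1.11 (adjusted p = 6.8e-05), each with an adjusted p of 0.439 with an estimated correlation. Without control replicate 2 their medians were -0.00 and -0.01, with adjusted p = 0.99 and 0.998. Endothelial (median 0.26, adjusted p = 0.00652) and squamous (median 0.26, adjusted p = 0.0218) lists also lost their calls without it, at adjusted p = 0.495 and 0.107 and medians of 0.11 and 0.12, and gave adjusted p = 0.503 and 0.439 with an estimated correlation. When LPS replicate 2 was left out too, the squamous list passed (adjusted p = 0.0333) and the endothelial list did not (adjusted p = 0.156). Without control replicate 1, the medians were -2.865 for pluripotency, -2.03 for proliferation, 2.39 for mesenchymal, 0.60 for endothelial and 0.52 for squamous genes, and 3.54 for the liver and gut list. Hypoxia and glycolysis (median 0.17, adjusted p = 0.0102; median 0.05 against control replicate 1 alone) and cholesterol synthesis (median 0.21, adjusted p = 0.0424) also passed, each with an adjusted p of 0.324 with an estimated correlation. Cholesterol synthesis lost its call without control replicate 1, with a median of 0.27 (adjusted p = 0.212), and without TNF-alpha replicate 1, with one of 0.22 (adjusted p = 0.0688), although neither median was smaller. Without control replicate 2 the median was 0.09 and the call held (adjusted p = 0.0405).

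By limma over all genes, 0 genes passed in TNF-alpha against control, with a smallest adjusted p of 0.148, and 0 passed by the unmoderated contrast (805 at an unadjusted p under 0.05). Chance would give 921 genes at an unadjusted p under 0.05 if the groups had a like spread, which the array pairs contradict. With moderation 908 genes had such a p, 509 of them higher. That number was 7059 without control replicate 1, and 191 and 179 without TNF-alpha replicates 1 and 2. The smallest p among genes with separated arrays belonged to SGPP2, a sphingosine-1-phosphate phosphatase (9.39-fold), CXCL8, CLDN1, C3, TNFRSF11B (3.25-fold), FCER1G, ABTB2 (3.18-fold), PTGS2, NCR3LG1 (3.01-fold) and IRF1, none of which passed. Both TNF-alpha arrays lay above both control arrays for 22.7% of genes and below for 25.8%. Chance gives 16.7% each only for arrays of like spread. The TNF-alpha pair was far closer than the control pair, so no excess over chance can be read from these shares. Without control replicate 1, which leaves control replicate 2 as the single control, 3575 genes passed, and without control replicate 2 the number was 0.

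**Figure D2:**
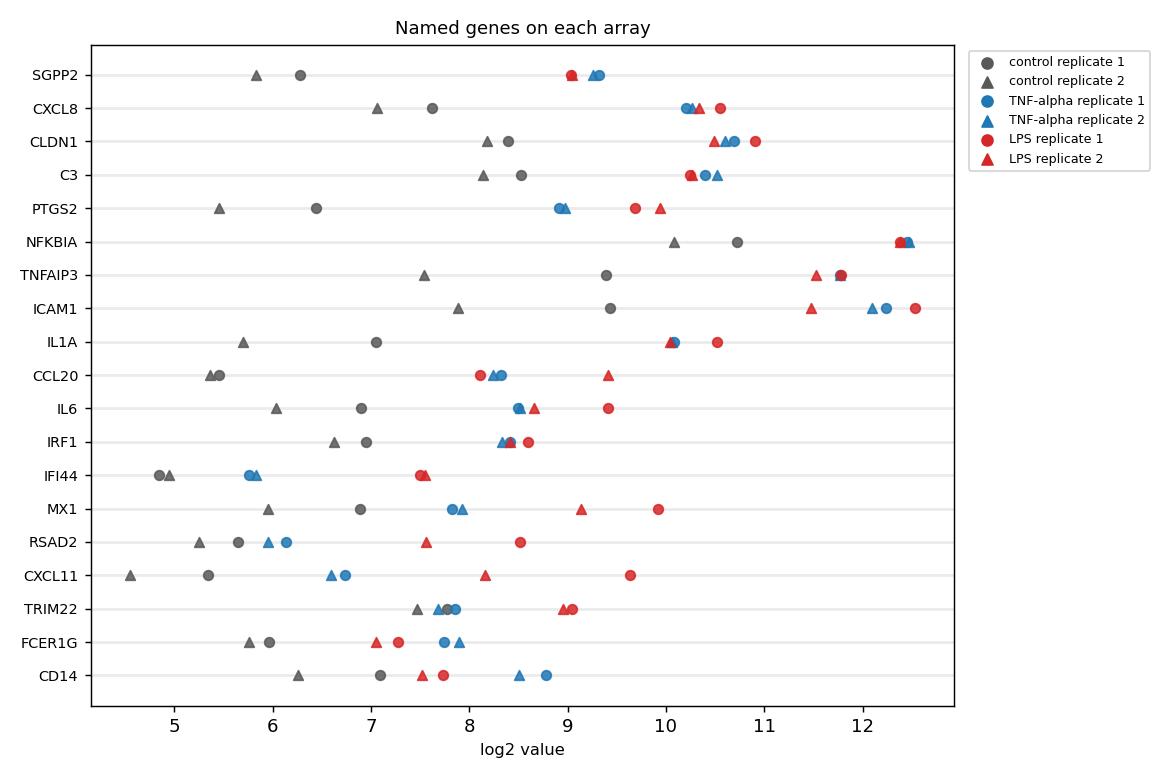
Log2 value (horizontal axis) of 19 named genes on each of the 6 arrays, colored by group, with circles for replicate 1 and triangles for replicate 2. For CXCL8 the control arrays lie at 7.62 and 7.06 and the 4 stimulated arrays between 10.20 and 10.55, and for IFI44 the LPS arrays lie at 7.50 and 7.55, above the TNF-alpha arrays at 5.76 and 5.83.

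LPS against control asked the same of the bacterial ligand. Interferon-stimulated genes stood first: all 37 measured members lay above control in mean. Both LPS arrays exceeded both control arrays for 36 of them, against 11.7% of all genes tested. Of the 37, 32 passed when adjusted over the list alone and 0 over all genes. IFI44 was at 4.89 ± 0.07 in control and 7.53 ± 0.04 after LPS, a 6.21-fold difference. IFI44L was 12.9-fold higher, MX1, an antiviral GTPase, 8.62-fold, and IRF1, a transcription factor, 3.30-fold. The median difference was 1.92 log2 units, with a camera adjusted p of 2.34e-43 (adjusted p = 0.222 with an estimated correlation). Of 12 MHC class I genes, TAP1, TAP2 and the immunoproteasome gene PSMB9 passed over their list, at 4.50-fold, 1.80-fold and 1.70-fold (camera adjusted p = 1.18e-07; adjusted p = 0.222 with an estimated correlation). That number was 8 without control replicate 1, 2 without control replicate 2 and 1 without any single TNF-alpha or LPS array, while 23 to 33 interferon-stimulated genes passed over their list when 1 array was left out.

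The NF-kB list was higher to a like degree as after TNF-alpha, with a median of 1.54 log2 units, 1.28 against control replicate 1 alone, and 22 of 27 members passing over the list alone (camera adjusted p = 5.41e-30; adjusted p = 0.222 with an estimated correlation). PTGS2 was 14.6-fold higher, REL 3.18-fold and TNIP1 2.32-fold, and NFKBIA was at 12.38 ± 0.00 against 10.40 ± 0.45. TNFAIP3 was 9.12-fold higher than the mean of control arrays that differed widely for it. Control replicate 2 held the lowest value of the 6 arrays for 23 of the 27 members. For those, folds against control replicate 1 alone would be smaller. Of 36 cytokines and chemokines, 19 passed over the list (camera adjusted p = 4.38e-23; adjusted p = 0.222 with an estimated correlation). CXCL8 was 8.60-fold higher, IL1A 15.0-fold, CCL20 10.2-fold and IL6 5.95-fold, and CXCL11, a ligand of the chemokine receptor CXCR3, was 15.4-fold higher. Of 20 adhesion and protease genes 8 passed, with PLAU 6.02-fold, MMP13 2.45-fold and ICAM1 10.2-fold higher (camera adjusted p = 3.84e-13; adjusted p = 0.222 with an estimated correlation). Leaving out 1 array gave 15 to 21 NF-kB genes, 13 to 26 cytokines and 3 to 12 adhesion genes over the list alone, the lowest without control replicate 2 for NF-kB genes, without LPS replicate 1 for cytokines and without LPS replicate 1 or either TNF-alpha array for adhesion genes. The adhesion median went from 1.19 to 0.59 without the second replicates of control and LPS.

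Of 27 antimicrobial genes, C3, S100A9 and CFB passed over the list, at 3.78-fold, 2.86-fold and 6.52-fold (camera adjusted p = 5.85e-13; adjusted p = 0.222 with an estimated correlation), and the median of 0.77 was 0.51 without control replicate 2 and also 0.51 without LPS replicate 2. Immediate-early genes had a median of 1.43 log2 units, and 6 of 27 passed over the list, among them DUSP6 at 2.88-fold, ZFP36 at 6.12-fold, KLF6 at 2.53-fold and JUN at 2.52-fold (camera adjusted p = 3.51e-19; adjusted p = 0.222 with an estimated correlation). On this list LPS replicate 2 stood 0.95 log2 units above LPS replicate 1 in mean, and the median was 0.78 without LPS replicate 2. The numbers passing over the list alone were 9 antimicrobial and 17 immediate-early genes without LPS replicate 1, 1 and 0 without LPS replicate 2, 10 and 14 without control replicate 1 and 2 and 8 without control replicate 2, and 0 immediate-early genes passed without either TNF-alpha array. FCER1G, at 2.47-fold, was the single one of 15 leukocyte markers to pass over its list (camera adjusted p = 7.5e-08; adjusted p = 0.33 with an estimated correlation), and the median of 0.44 was 0.19 without LPS replicate 1. Over their lists, 5 leukocyte markers and 3 LPS-sensing genes passed without control replicate 1, 2 and 1 without LPS replicate 2, and 0 of either without LPS replicate 1. In LPS sensing 0 of 17 genes passed over the list (camera adjusted p = 3.45e-05; adjusted p = 0.222 with an estimated correlation), with a median of 0.47, which was 0.26 against control replicate 1 alone and 0.23 without LPS replicate 1. CD14 stood at 7.63 ± 0.15, TLR4 at 5.85 and 6.14 on the LPS arrays and LY96 at 4.49 ± 0.31 after LPS. In TNF receptor signalling, MAP3K8 passed over the list at 2.56-fold, and TNFRSF1A was at 10.33 ± 0.45 (camera adjusted p = 0.0191; adjusted p = 0.222 with an estimated correlation). The number passing over that list was 4 without control replicate 1, 0 without any single TNF-alpha or LPS array and 4 without the second replicates of control and LPS. That list's call was lost without LPS replicate 2 and without control replicate 1. Its medians there were 0.16 and 0.22, near the 0.20 of the full set, and its median was 0.01 without control replicate 2. Without the second replicates of control and LPS the medians were 0.32 for antimicrobial, 0.60 for immediate-early and 0.07 for TNF receptor signalling genes, and these calls held.

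CLDN1 was 5.33-fold higher after LPS, as the single junction gene to pass over its list, which did not pass as a set (adjusted p = 0.419) except without LPS replicate 1 (adjusted p = 0.00272). MUC1 was 2.00-fold higher, the single one of 18 secretory genes to pass over the list, and the membrane mucin gene MUC16 was 6.46-fold higher (camera adjusted p = 2.18e-06; adjusted p = 0.222 with an estimated correlation). The secretory median went from 0.37 to 0.20 without the second replicates of control and LPS. Over the lists, 6 secretory, 4 basal, 2 junction and 1 squamous genes passed without control replicate 1, 5 secretory, 3 basal and 10 squamous genes without LPS replicate 1, and 0 secretory genes without LPS replicate 2 or either TNF-alpha array. No ciliated gene (adjusted p = 0.386) and no basal gene (adjusted p = 0.0613) passed. The basal list passed without LPS replicate 1 (adjusted p = 0.0158) and without either TNF-alpha array (adjusted p = 0.0493). FOXJ1 was at 7.16 ± 0.14 after LPS and SCGB1A1 at 6.92 ± 0.13. KRT5 was at 9.68 ± 2.93 and CFTR at 6.69 ± 1.52, with KRT5 at 7.61 and 11.75 and CFTR at 5.61 and 7.76 on LPS replicates 1 and 2. Squamous genes had a median of 1.16 (adjusted p = 4.2e-06; 0.222 with an estimated correlation), with 0 members passing over the list, and LPS replicate 2 stood 1.16 log2 units above LPS replicate 1 in mean. The squamous median was 0.36 without LPS replicate 2 (adjusted p = 0.00189), 1.90 without LPS replicate 1 and 0.12 without the second replicates of control and LPS (adjusted p = 0.0271). Lung endoderm genes (median 0.20, adjusted p = 0.00129; 0.33 with an estimated correlation) lost their call without LPS replicate 2, with a median of 0.18 (adjusted p = 0.104), and without the second replicates of control and LPS, with one of 0.06 (adjusted p = 0.49), and had a median of 0.48 without LPS replicate 1. Ion and water transport (median 0.17, adjusted p = 0.0157; 0.33 with an estimated correlation) lost it without LPS replicate 1, with a median of 0.12 (adjusted p = 0.0782). Against control replicate 1 alone the medians of the lung and transport lists were 0.09 and 0.10, and without control replicate 1 they were 0.37 and 0.31. Cholesterol synthesis (median 0.12, adjusted p = 0.0478; 0.249 with an estimated correlation) lost it without either control array or without LPS replicate 2, with adjusted p of 0.221 and 0.065 without control replicates 1 and 2 and 0.373 without LPS replicate 2. Its medians there were 0.22, 0.13 and 0.16, and 0.03 without the second replicates of control and LPS (adjusted p = 0.477).

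The lists that moved with control replicate 2 did so here too. Pluripotency markers had a median of -1.63 (adjusted p = 1.4e-05; 0.437 with an estimated correlation) and -0.13 without control replicate 2 (adjusted p = 0.00973). When LPS replicate 2 was left out too, it was -0.05 and the call was lost (adjusted p = 0.255). Proliferation genes had a median of -1.01 (adjusted p = 1.02e-06; 0.475 with an estimated correlation), of -0.04 without control replicate 2 (adjusted p = 0.808), of -0.66 without LPS replicate 1 and, without the second replicates of control and LPS, of -0.42, where they passed (adjusted p = 8.95e-07). For the liver and gut list the median was 1.32 (adjusted p = 2.88e-05; 0.45 with an estimated correlation), and -0.07 without that array (adjusted p = 0.434). Mesenchymal markers went from 0.78 (adjusted p = 0.00508; 0.499 with an estimated correlation) to -0.43 without it (adjusted p = 0.00109), and lost their call without LPS replicate 1, with a median of 0.44 (adjusted p = 0.195). Without the second replicates of control and LPS, the liver and gut median was -0.06 (adjusted p = 0.0885) and the mesenchymal median -0.06 (adjusted p = 0.614). Without control replicate 1 the medians were -3.21 for pluripotency, -2.02 for proliferation, 1.99 for mesenchymal genes and 3.16 for the liver and gut list. Neural (adjusted p = 0.0752), hypoxia (0.0912), endoplasmic reticulum stress (0.161), housekeeping (0.26), oxidative stress (0.393) and endothelial (0.465) lists did not pass. Hypoxia passed without control replicate 1 (adjusted p = 0.0226). Without LPS replicate 1, leaving LPS replicate 2, neural genes passed as higher with a median of 0.68 (adjusted p = 2.83e-07), while without the second replicates of control and LPS they passed as lower with one of -0.25 (adjusted p = 0.00327). Without LPS replicate 1 endoplasmic reticulum stress genes passed as well, with 0.12 (adjusted p = 0.00495). Endothelial genes passed as lower without LPS replicate 1, at -0.35 (adjusted p = 0.0249), and as higher without LPS replicate 2, at 0.30 (adjusted p = 0.00391).

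By limma 0 genes passed in LPS against control, with a smallest adjusted p of 0.102 for IFI44, and 0 passed by the unmoderated contrast (813 at an unadjusted p under 0.05). As above, the 921 genes that chance would give at an unadjusted p under 0.05 presume a like spread in every group. With moderation 947 genes had such a p, 538 of them higher. That number was 6580 without control replicate 1, and 383 without either TNF-alpha array or with only the groups compared. Both LPS arrays lay above both control arrays for 11.7% of genes and below for 16.5%. Chance gives 16.7% each only for arrays of like spread, which the array pairs contradict. Below IFI44 in p, among genes with separated arrays, came SGPP2 (7.91-fold), CXCL8, CLDN1, PTGS2, CCL4 (4.14-fold), C3, PARP14 (3.16-fold), the macrophage elastase gene MMP12 (3.07-fold) and IRF1. Without control replicate 1, 3390 genes passed, and without control replicate 2 the number was 0.

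TNF-alpha against LPS asked where the stimuli differed. Interferon-stimulated genes were lower after TNF-alpha than after LPS, and all 37 lay below in mean. For 34 both TNF-alpha arrays lay under both LPS arrays, against 13.1% of all genes tested. When adjusted over the list alone, 8 passed. IFI44 was at 5.79 ± 0.05 after TNF-alpha and 7.53 ± 0.04 after LPS, and RSAD2, which encodes the antiviral enzyme viperin, at 6.04 ± 0.13 and 8.04 ± 0.67. TRIM22 was 2.34-fold and IFI44L 4.39-fold lower after TNF-alpha. The median difference was -0.98 log2 units, with a camera adjusted p of 5.3e-52 (adjusted p = 0.58 with an estimated correlation). It was -1.47 against LPS replicate 1 alone and -0.64 against LPS replicate 2 alone. The number passing over the list alone was 0 without either TNF-alpha array, 1 without LPS replicate 1, 21 without LPS replicate 2 and 23 without either control array. The NF-kB list did not pass (adjusted p = 0.755), with a median of 0.12 and 18 of 27 members above.

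Cytokines and chemokines were lower after TNF-alpha by a median of -0.16 (adjusted p = 0.00119; 0.67 with an estimated correlation), with CXCL11 4.69-fold lower, CXCL9 1.95-fold lower and 0 of 36 passing over the list. The number passing was 3 without LPS replicate 1, 2 without LPS replicate 2 and 15 without the second replicates of control and LPS. That list's call was lost without LPS replicate 1, with a median of 0.03 (adjusted p = 0.386). The call of MHC class I genes (median -0.13, adjusted p = 0.0112; 0.67 with an estimated correlation) was lost there too, with a median of -0.06 (adjusted p = 0.52), and their median was -0.20 without LPS replicate 2. Immediate-early genes (median -0.60, adjusted p = 4.98e-10), neural (-0.49, 7.96e-07), squamous (-0.81, 0.000232), secretory (-0.07, 0.00325), epithelial junction (-0.14, 0.00879) and lung endoderm (-0.09, 0.0421) lists were lower after TNF-alpha. Leukocyte (0.22, 4.29e-05), endothelial (0.43, 0.00121), pluripotency (0.30, 0.00605) and mesenchymal (0.42, 0.0192) lists were higher. All 10 lost their calls without LPS replicate 2, with adjusted p between 0.111 and 0.97. The medians of 7 of them then lay between -0.09 (neural) and 0.08 (epithelial junction), whereas those of secretory genes, at -0.10, lung endoderm genes, at -0.08, and pluripotency genes, at 0.25, stayed near their values in the full set. Without the second replicates of control and LPS, secretory (adjusted p = 0.028) and pluripotency (1.37e-07) lists passed, the other 8 did not (adjusted p between 0.07 and 0.873), and proliferation (median 0.21, adjusted p = 9.03e-07) and liver and gut (0.12, 0.0235) lists passed as higher. Without LPS replicate 1, pluripotency (median 0.41, adjusted p = 0.069), mesenchymal (0.85, 0.0556) and lung endoderm (-0.17, 0.069) lists lost their calls with larger medians. The medians of immediate-early (-1.11), neural (-0.89), squamous (-1.50), junction (-0.27), leukocyte (0.36) and endothelial (0.72) lists were larger in size there too, and their calls held. The lung list had a median of -0.18 without TNF-alpha replicate 1. It lost its call without either control array, which leaves its median of -0.09 as it was, and without TNF-alpha replicate 2. The junction list also lost its call without TNF-alpha replicate 2. With an estimated correlation, the adjusted p of the 13 lists that passed ranged from 0.58 to 0.758, and 15 lists did not pass with the preset one. CD14 was 2.02-fold higher after TNF-alpha than after LPS and did not pass. By limma 0 genes passed, with 103 at an unadjusted p under 0.05 (chance 921) and a smallest adjusted p of 0.945, and 0 passed by the unmoderated contrast (269 unadjusted). The moderated number of 103 was 923 without LPS replicate 1, 22 and 20 without TNF-alpha replicates 1 and 2, and 363 without either control array or with only the groups compared. The fit shared 1 spread per gene over all groups, so the wide control pair entered a comparison that holds no control array. The test may thus be too cautious here, and a number under chance is not evidence that the stimuli acted alike. Both TNF-alpha arrays lay above both LPS arrays for 17.1% of genes and below for 13.1%. Chance gives 16.7% each only for arrays of like spread, which the array pairs contradict. Next to IFI44, TRIM22, RSAD2, IFI44L and CXCL11, the smallest p among genes with separated arrays belonged to EIF2AK2 (1.77-fold lower after TNF-alpha), SAMD9 (4.02-fold), DDX60 (1.86-fold), AQP9 (1.94-fold) and MX1 (3.15-fold), and none passed.

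Across genes, which are not independent replicates, the differences from control after TNF-alpha and after LPS correlated with Pearson r = 0.868 and Spearman rho = 0.861. Unchanged groups sharing the same controls, each group with its own spread per gene, gave r = 0.829 ± 0.00549 and rho = 0.723 ± 0.00466 in 100 simulations (mean ± SD). The covariance was 0.201, against 0.153 ± 0.00509 in the simulations, a difference of 0.0476, and the spread of the controls in them rests on 1 pair of arrays. Simulations with a like spread in every group, which the array pairs contradict, gave r = 0.501 and a covariance of 0.0735. The use of each group's own spread was chosen after the values were seen. Genes varied independently in these simulations, whereas the estimated inter-gene correlation was 0.421 for interferon-stimulated and 0.975 for proliferation genes. Their SDs are thus too narrow for genes that move together. Whether the observed r, rho and covariance exceed what the shared controls give cannot be decided from them. Without control replicate 2 r was 0.660 and without LPS replicate 1 it was 0.583. Of the genes with an unadjusted p under 0.05 and a difference of at least 1.5-fold, 272 were higher in both comparisons, from 416 after TNF-alpha and 463 after LPS. In the lower direction 103 were shared, from 255 and 265. The simulations of unchanged groups with their own spreads shared 308 ± 17.1 higher genes, from 390 and 584, and 311 ± 16.3 lower ones, from 392 and 582. Since 3 of these 4 simulated lists were longer than the observed ones, the shared counts cannot be compared directly, and whether the overlap exceeds what the shared controls give stays open. Independent lists, which leave the shared controls out, would share 10.5 and 3.67. The controls could not be split into sets of 2 arrays. With control replicate 1 for TNF-alpha and control replicate 2 for LPS, r was 0.292, and the reverse assignment was not computed. The LPS differences then rest on the array that stood apart, so this r does not measure the likeness of the stimuli alone.

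**Figure D3:**
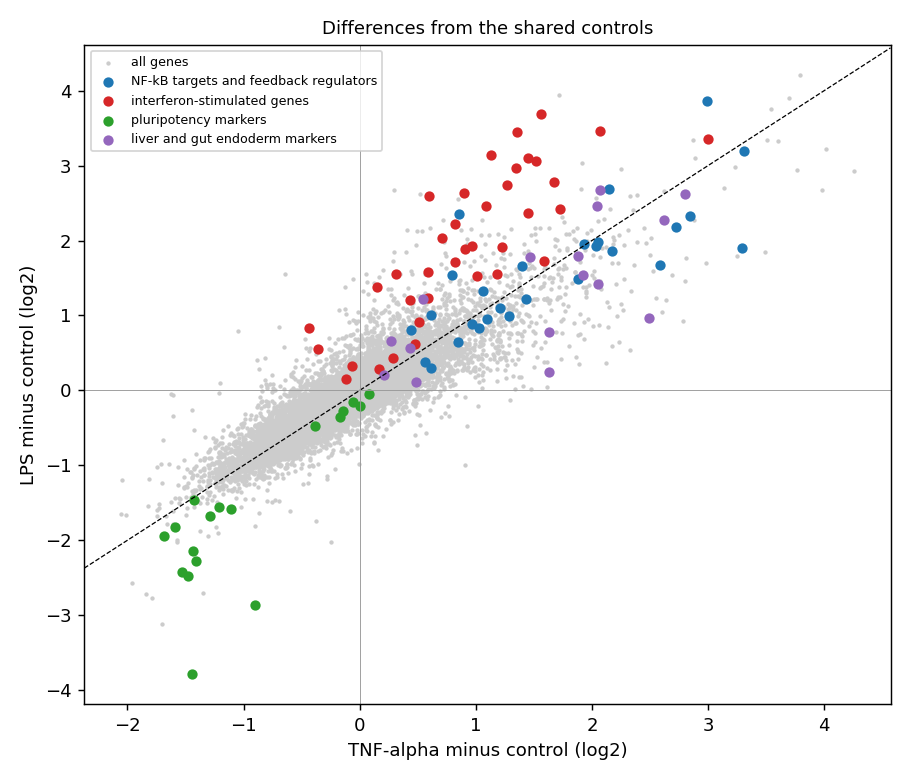
Difference from control in log2 units after TNF-alpha (horizontal axis) and after LPS (vertical axis) for 18417 genes in gray, with members of 4 gene lists in color and a dashed line of equal differences. All 37 interferon-stimulated genes lie above the line, and the pluripotency and liver lists have medians of -1.25 and 1.76 after TNF-alpha.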

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

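The fit of replicate 1 of control and LPS with both TNF-alpha arrays, and array weights, were chosen after seeing the data. The counts of genes stayed at 0 in all 3 comparisons with the replicate block (1507, 1349 and 137 at an unadjusted p under 0.05), with only the groups compared, with a trended or robust prior, without moderation, without the dimmest genes, with the mean of rows, with every row on its own and with both other normalizations. Deviations of same-numbered arrays from their group means correlated at r = 0.443 for control and LPS. For control and TNF-alpha r was 0.0296, and for TNF-alpha and LPS 0.0657, both under 0.1. The series' design text speaks of paired cells without saying whether a number marks a shared differentiation, so pairing stays open, and the numbers were not taken as pairs. The block changed no call of a gene. With it 18, 18 and 12 lists passed. It ended the calls of cholesterol synthesis after TNF-alpha (adjusted p = 0.0577) and after LPS (0.0578) and of lung endoderm genes between the stimuli (0.0593), and ion and water transport passed after TNF-alpha (0.0448). Leaving out 1 array gave 0 to 3575 genes in TNF-alpha against control, 0 to 3390 in LPS against control and 0 in TNF-alpha against LPS; the high counts came without control replicate 1, when a single array carried the control. Replicate 1 of control and LPS with both TNF-alpha arrays gave 1676, 2406 and 479 genes, with the spread taken from the TNF-alpha pair alone, which may be technical (4477, 5327 and 3575 at an unadjusted p under 0.05). Array weights gave 1, 0 and 0 genes (1252, 609 and 438 at an unadjusted p under 0.05). The weights were equal within each pair, at 0.282 for control, 5.69 for TNF-alpha and 0.624 for LPS. They could therefore not set control replicate 2 or LPS replicate 2 against its partner. Unadjusted p with a 1.5-fold change gave 671, 728 and 62 genes.

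Of 28 lists, 18, 19 and 13 passed in the 3 comparisons. With an estimated correlation and with directional fry 0 passed in each, and with mixed fry 5, 8 and 0. Leaving out 1 array gave 14 to 21, 16 to 22 and 3 to 13 lists, and replicate 1 of control and LPS with both TNF-alpha arrays gave 7 in TNF-alpha against LPS. The pluripotency list in TNF-alpha against control ranged from -2.865 without control replicate 1 to 0.1819 without control replicate 2, and was 0.1819 also without the second replicates of control and LPS; the mesenchymal list in LPS against control ranged from -0.4347 without control replicate 2 to 1.993 without control replicate 1. TPPP3, a ciliated cell gene, turned to -0.63 in LPS against control without those replicates. The correlation of the differences ranged from 0.583 to 0.956 when 1 array was left out. The cause was not tested. Another scaling moved the median of all genes by between -0.0548 and -0.00155 log2 units. Of 361 pairs of named gene and comparison, 11 turned direction without control replicate 2, 16 without LPS replicate 2 and 3 without LPS replicate 1. Without the second replicates of control and LPS 29 turned direction without passing, and 1 further pair turned direction too. No signal over background was used here, so what dim genes can show stays limited.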

Other observations

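The array labelled LPS replicate 2 carried transcripts that the other arrays held at lower levels. KRT5 stood at 11.75, against 6.51 to 7.61 on the others, S100A8 at 9.97 against 5.33 to 6.53, LCN2 at 10.62 against 6.97 to 7.76 and AGR2 at 8.55 against 4.38 to 5.41. The immediate-early genes EGR1 and FOSB stood at 13.11 and 10.70, against 10.56 and 7.75 on LPS replicate 1. Of 18 squamous genes 12 and of 17 neural genes 10 had their highest value on it, and ZIC1 was at 10.64 against 6.90 on LPS replicate 1. KDR, an endothelial receptor, was at 6.79 against 10.22. These genes were chosen after their values were seen.

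LIN28A and CRIPTO, both of the pluripotency list, stood higher on the TNF-alpha arrays than on control replicate 1 and both LPS arrays. LIN28A was at 9.37 and 9.36 after TNF-alpha, 8.19 on control replicate 1 and 7.82 and 6.99 after LPS, and CRIPTO at 6.82 and 6.19 against 4.14, 4.19 and 4.13. These genes, too, were chosen after their values were seen. The list had a median of 0.18 without control replicate 2 (camera adjusted p = 4.76e-06; 0.382 with an estimated correlation), and 1 of 18 members passed over the list. Against LPS 0 of 18 passed, or 7 without either control array, and the camera call (adjusted p = 0.00605; 0.72 with an estimated correlation) was lost without either LPS array.

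The tests below were chosen after the result was seen, except that of IFNB1. Control replicate 2 stands apart in lineage markers. A difference of array scale is argued against, since the pluripotency list exceeded 200 genes of equal level on control replicate 1 by a median of 3.11 log2 units (SD over members 2.06) and the liver list differed by -3.72 (SD 1.71). RNA mostly from undifferentiated cells may account for the pattern: 17 of 18 pluripotency markers had their highest and 16 of 16 liver and gut markers their lowest value there. A wrong label and a culture that differentiated less cannot be told apart: that 9 of 20 mesenchymal markers lay above that array's upper quartile of 8.78 sets different probes against each other and decides nothing, and no reference array of undifferentiated CA2 cells was analysed here.

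Interferon-stimulated genes were higher after LPS than after TNF-alpha. LPS replicate 2 alone is argued against, since 37 of 37 members lay above both TNF-alpha arrays on LPS replicate 1 and 34 on LPS replicate 2. A stronger response to LPS was not seen in the NF-kB list, whose median TNF-alpha minus LPS was 0.116 (SD over 27 members 0.563), against -0.98 for the interferon list. Adhesion genes (0.13) ran the same way as the NF-kB list, but cytokines (-0.16) and immediate-early genes (-0.60) were lower after TNF-alpha. The cytokine median was 0.03 against LPS replicate 2 alone, and the immediate-early one -0.05 against LPS replicate 1 alone. Whether the response to LPS was stronger as a whole stays open, and 1 dose of each stimulus leaves the ligand and its dose confounded. A candidate explanation is interferon beta made after LPS. IFNB1 lay at 3.86 to 3.90 on the stimulated arrays and differed by 0.0244 log2 units, and stood at 3.852 and 3.865 on the control arrays. These values lie below the 10th percentile of genes on every array (5.095 to 5.312), so they may be background and decide nothing. Interferon beta thus cannot be told apart from an earlier or unmeasured signal at 5 hours. Among other interferon genes, LPS minus TNF-alpha was -0.26 for IFNL1, -0.23 for IFNL2, -0.12 for IFNL3 and 0.08 for IFNG, so none of these 3 IFNL transcripts was higher after LPS in mean.

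All 15 leukocyte markers lay above control in mean after TNF-alpha and after LPS, with 6 and 1 passing over the list in the full set. Against control replicate 1 alone the median was 0.534 after TNF-alpha (SD over members 0.556) and 0.308 after LPS. Medians thus stayed above control replicate 1, which cannot decide whether control replicate 2, by lowering the control mean, makes up the whole difference. What remains rests on 1 control array, and the SD shows how members differ rather than how precise the median is. Whether it is a rise with the stimulus stays open. A larger share of leukocyte-like cells may contribute, since 14 of 15 markers lay above control replicate 1 on both TNF-alpha arrays, with LAPTM5 at 9.09 and 9.01 against 7.74. A like amount for every marker was not seen, and induction within cells already present cannot be told apart from it.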
